A study of Homo sapiens with 12 samples.

How the data were processed

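RNA was measured in 12 libraries of MOLT4 cells, 3 each of DMSO, SNS-032, THAL-SNS-032 and NVP-2. Per the labels, spike-in RNA (ERCC) was added at cell lysis, poly(A) RNA was selected and stranded libraries were made. The authors aligned reads with HISAT to hg19 and computed FPKM with Cufflinks 2.0.0, and the annotation is not stated. The deposited values are FPKM per gene on a scale that the authors set across libraries. How the spike-ins entered it is not stated, but the ERCC values are level between libraries and the genes are not. No value is 0, and 4214 names share 1 value per library, between 0.0910 and 0.104 FPKM. The table gives no counts, so depth and counting error are unknown and no interval that needs them is given.

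Of 23713 entries, 92 ERCC entries and 2 repeated symbols were removed, which left 23619 genes, 28 of them with names turned into dates. Genes with a mean of 1 FPKM or more over the 12 libraries were tested (11381). Values were used on the deposited scale as log2(FPKM + 1), without further normalization. One limma 3.58.1 fit in R 4.3.3 with trend, over the 4 groups and with 8 residual degrees of freedom, gave 6 two-sided comparisons, each compound with DMSO and each pair of compounds. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the 95% interval of each difference was set against 2-fold between compounds. Library medians were compared by exact two-sided permutation, whose smallest p is 0.1 for 3 against 3.

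Of 30 gene lists, 24 had 5 or more tested members and were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted within each comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way. The estimated correlation comes from residuals of the fit, where on the deposited scale a shift of a whole library moves all genes together. Such a shift raises it for any list, so a call lost there need not reflect a correlation particular to the list. Named genes come from a rule: for each comparison the 6 largest rises and falls among called genes whose groups do not overlap, short RNAs and unnamed loci left out, up to 3 called members and the highest-expressed member of each list, and a set that included CDK9, MYC and MCL1. The genes printed were picked from those the rule allows after their values were seen, and any named outside it are said to be. Groups, comparisons, tests, lists, this rule and the first set of alternatives were chosen before the data were examined.

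Alternatives changed 1 choice at a time, except the estimated correlation on median-centred libraries, which changed 2: a pseudocount of 0.1 or 5, no filter or a mean of 5 FPKM, median-centred or quantile-normalized libraries, equal ERCC medians, limma without trend or with robust, only the 6 libraries of a pair, a replicate block, a 2-fold minimum, an interval of 1.5-fold, each replicate left out, and the other list tests. Chosen after seeing the data were centring on the median change from DMSO, leaving out short RNAs and unnamed loci, and the estimated correlation on median-centred libraries. Where a left-out replicate leaves 2 libraries in a group, the pooled spread of all groups is used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

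The test was checked on data simulated around the DMSO means with the residual spread of each gene over the 4 groups. Among 11381 genes 200 were changed, picked from those not low in DMSO, and the G2/M list was raised 2-fold. Far fewer genes changed than in the real comparisons with DMSO, so these rates may not carry over to them. For SNS-032 against DMSO it recovered 28.4%, 83.6% and 97.0% of changes of 1.5-, 2- and 4-fold with 6 false calls, and 0%, 52.2% and 98.5% with 2 false calls when libraries were offset as observed. For THAL-SNS-032 against SNS-032 it recovered 29.9%, 74.6% and 100% with 2 false calls, and 2.99%, 56.7% and 98.5% with 0 with such offsets. The residual spread already holds these offsets, so adding them counts them again, and the rates with offsets do not describe the real data.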

Results

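Poly(A)-selected, stranded RNA sequencing measured transcript levels in MOLT4 cells, an established human T-cell acute lymphoblastic leukemia (T-ALL) line, after 6 h in 0.1% DMSO, the vehicle, or in 250 nM of 1 of 3 compounds. SNS-032 inhibits several cyclin-dependent kinases, among them CDK9, the catalytic subunit of the elongation factor P-TEFb. THAL-SNS-032 is SNS-032 linked to a thalidomide-type ligand of cereblon, the substrate receptor of a ubiquitin ligase, and NVP-2 is an inhibitor of CDK9. Each of the 4 groups had 3 libraries, 12 in all. Of 23619 gene names, 11381 had a mean of 1 FPKM or more and were tested. Read depth is unknown, because the table holds FPKM and no counts. Levels are given as mean ± SD of 3 libraries. Changes are differences in mean log2(FPKM + 1), with the SE of the fit where it is given, and this scale understates changes of genes near the floor of about 0.1 FPKM. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. That spread is pooled over the 4 groups, so the SE of every comparison also takes in the SNS-032 libraries, which differed most.

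The comparisons with DMSO asked which transcripts each compound changed within 6 h. On the deposited scale, on which the spike-in RNAs (ERCC) added at lysis were level between libraries, the median gene was lower with each compound than in DMSO. The library medians lay -1.92 ± 0.35 (log2, SD, n = 3) from the DMSO mean with SNS-032, -1.90 ± 0.087 with THAL-SNS-032 and -2.54 ± 0.081 with NVP-2, and the SD between DMSO libraries was 0.091. Spike-in medians stayed between -0.031 and 0.039. In DMSO 12083 ± 109 genes reached 1 FPKM, against 9956 ± 711 with SNS-032, 9914 ± 204 with THAL-SNS-032 and 8491 ± 232 with NVP-2. All 3 libraries of each compound lay below all 3 DMSO libraries (exact two-sided permutation p = 0.1 for each compound, the smallest that 3 against 3 allows). SNS-032 replicate 1 stood apart from its group at -2.32, against -1.68 and -1.77 for replicates 2 and 3. Centring each library on its own median moved the median changes to 0.25, 0.36 and 0.42 for SNS-032, THAL-SNS-032 and NVP-2. A centred change from DMSO that is above 0 but under these values is thus still below that of the median gene. Centring takes out a shift of all genes, so a gene that fell by less than that shift turns positive by construction. Such a reversal does not test the fall on the deposited scale.

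**Figure D1:**
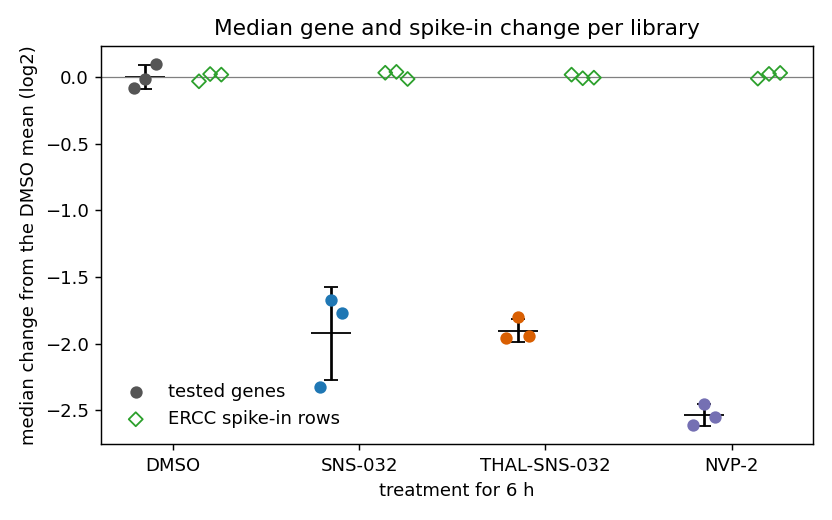
Median change from the DMSO mean (log2, vertical axis) of tested genes (filled points) and ERCC spike-in RNAs (open diamonds) in each library of the 4 treatment groups, where black bars are the mean and SD of 3 libraries. Gene medians with the compounds lie between -2.61 and -1.68, while spike-in medians lie between -0.031 and 0.039.

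With SNS-032, transcripts central to this leukemia fell by very different amounts. MYC, a proto-oncogene transcription factor, fell from 331 ± 27.4 to 145 ± 39.3 FPKM (-1.22, SE 0.20), and the survival factor MCL1 fell from 92.9 ± 6.63 to 48.5 ± 14.9. MYB, a transcription factor of immature blood cells, fell from 455 ± 41.8 to 52.3 ± 16.7, and TAL1, a T-ALL oncogene, fell from 29.9 ± 2.53 to 2.47 ± 0.837. GATA3, a T-lineage transcription factor, fell from 30.5 ± 2.48 to 15.4 ± 4.13. After centring, MYC, MCL1 and GATA3 turned to 0.96, 1.20 and 1.20. CDK9 fell from 36.1 ± 4.16 to 10.2 ± 2.97 (-1.76, but 0.41 after centring). Its cyclin partner CCNT1 was 26.8 ± 1.49 in DMSO and 21.7 ± 6.47 with SNS-032 and did not pass (-0.34, adjusted p = 0.0968, limma), but it passed without SNS-032 replicate 2 (-0.52) and turned to 1.83 after centring. POLR2A, the largest subunit of RNA polymerase II, and the survival factor BCL2 changed by -1.86 and -1.47, and by 0.31 and 0.70 after centring.

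Large falls with SNS-032 included GIMAP5, a lymphocyte GTPase (-5.84), NMI (-5.29) and BCAS2, a spliceosome component (-5.23). All 21 tested heat shock genes fell, also adjusted over the list alone (median -2.24, -0.064 after centring), with the chaperone gene HSPA8 going from 4162 ± 519 to 261 ± 76.1 FPKM and DNAJA1 from 949 ± 97.2 to 45.5 ± 13.5. All 22 tested integrated stress response genes fell, also adjusted over the list alone (median -2.53, -0.36 after centring), among them DDIT3 (-4.75) and XBP1 (-4.60). Of 18 tested P-TEFb control and pausing factors, 0 rose, 17 fell and 1 did not pass (0 and 17 adjusted over the list alone), with a median of -2.00 that became 0.17 after centring. Among them, MEPCE, which caps 7SK RNA, changed by -4.56 and HEXIM1, the 7SK-bound inhibitor of P-TEFb, by -2.73. Of 9 tested BCL2 and IAP survival genes, 0 rose, 8 fell and 1 did not pass (0 and 8 adjusted over the list alone), with a median of -1.39 that became 0.78 after centring. BIRC5, which encodes survivin, was 199 ± 16.7 FPKM in DMSO and 152 ± 43.0 with SNS-032 and did not pass (-0.43, adjusted p = 0.0566, limma), but it passed without SNS-032 replicate 2 (-0.57) or 3 (-0.55) and turned to 1.74 after centring. LDHA, a glycolytic enzyme gene, SRSF3, a splicing factor gene, and PCNA, the replication clamp gene, changed by -3.87, -4.33 and -2.81.

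A smaller set rose with SNS-032. RASL11A, a RAS-like GTPase gene, went from 1.26 ± 0.436 to 26.0 ± 6.60 FPKM, PHLDA1 went from 0.552 ± 0.0460 to 14.3 ± 3.76, and APOE, which encodes an apolipoprotein, rose by 2.86 on the log2 scale. Of 23 tested p53 target genes, 5 rose, 14 fell and 4 did not pass (5 and 14 adjusted over the list alone). The 5 that rose, named after their values were seen, were TP53INP1 (1.63), BBC3, which encodes the death-promoting protein PUMA (1.25), ZMAT3 (1.21), AEN (0.74) and SESN1 (0.63). The median of the list was -1.37, and 0.81 after centring. Of 53 tested histone genes, 6 rose, 11 fell and 36 did not pass (3 and 9 adjusted over the list alone), with a median of -0.062 that became 2.11 after centring, while the linker histone genes H1F0 and H1FX, whose transcripts carry poly(A) tails, changed by -3.32 and -2.49. Of 77 tested cytosolic ribosomal protein genes, 0 rose, 75 fell and 2 did not pass (0 and 75 adjusted over the list alone), with a median of -0.96 that became 1.21 after centring. RPL4 changed by -1.72 and RPS27 by -0.83, and by 0.45 and 1.34 after centring.

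Camera, which ranks a list against the other genes, placed p53 targets (adjusted p = 3.83e-11), histone genes (2.36e-51) and ribosomal proteins (8.83e-06) above them with SNS-032. None of these 3 calls held with an estimated correlation (adjusted p = 0.997, 0.0916 and 0.997). The low level of SNS-032 replicate 1 across genes raises that correlation for any list, so this loss alone cannot decide. They did not hold on median-centred libraries either (camera, adjusted p = 0.168 to 0.791), an alternative chosen after the data were seen. Across all genes, limma with Benjamini-Hochberg adjustment called 175 genes higher and 10761 lower, 9897 of the latter by at least 2-fold, and after centring the split was 5989 higher and 3537 lower. Of the genes called higher on the deposited scale, 46 were short RNAs or unnamed loci and 6 were histone genes.

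**Figure D2:**
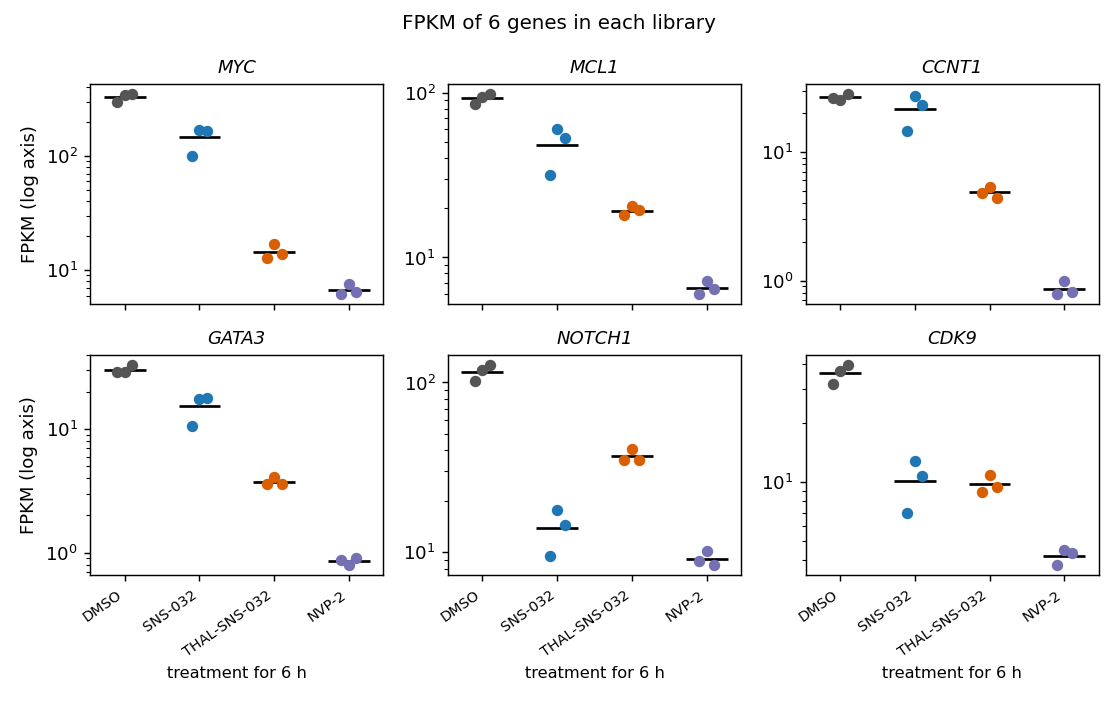
FPKM (log axis) of MYC, MCL1, CCNT1, GATA3, NOTCH1 and CDK9 in each of the 12 libraries by treatment for 6 h, where points are libraries and bars are means of 3. NOTCH1 has a mean of 37.0 with THAL-SNS-032, 13.9 with SNS-032 and 9.15 with NVP-2, whereas MYC, MCL1, CCNT1 and GATA3 are lower with THAL-SNS-032 than with SNS-032.

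With THAL-SNS-032, MYC fell from 331 ± 27.4 to 14.6 ± 2.16 FPKM (-4.42, SE 0.20), MYB fell to 26.4 ± 2.39 and GATA3 to 3.75 ± 0.307. MCL1 fell to 19.3 ± 1.26 (-2.21, and 0.048 after centring, where the median gene was at 0.36). HES1, a target gene of NOTCH1 signalling, fell from 56.7 ± 4.28 to 2.59 ± 0.409. NOTCH1 itself fell from 116 ± 12.8 to 37.0 ± 3.33 on the deposited scale and was 0.64 after centring. CDK9 fell to 9.78 ± 1.04 (-1.78, but 0.48 after centring) and CCNT1 to 4.84 ± 0.459 (-2.25, and 0.0053 after centring, below the median gene). CDK7, the kinase gene of TFIIH, fell from 43.4 ± 1.03 to 1.28 ± 0.170. Large falls included the ribosome biogenesis genes MPHOSPH10 (-5.30), NGDN (-5.29) and NOP16 (-5.15), and GTF2B, a general transcription factor gene (-5.16). Among genes that rose, MGP, which encodes a matrix protein, went from 0.190 ± 0.00702 to 15.3 ± 1.29, RCVRN, a photoreceptor calcium sensor gene, from 0.531 ± 0.230 to 11.6 ± 1.35, MIA from 0.460 ± 0.264 to 9.93 ± 0.912, and RASL11A from 1.26 ± 0.436 to 23.7 ± 2.25.

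Of 16 tested transcriptional CDK and cyclin genes, 0 rose, 15 fell and 1 did not pass (0 and 15 adjusted over the list alone), with a median of -2.29, -0.036 after centring. Of 15 tested TAL1-centred transcription factors, 1 rose, 14 fell and 0 did not pass (1 and 14 adjusted over the list alone), with a median of -2.50, -0.24 after centring. All 10 tested NOTCH1 pathway genes fell, also adjusted over the list alone, but the median of -1.52 became 0.74 after centring. All 15 tested genes of the cereblon ligase and of thalidomide-analogue substrates fell, also adjusted over the list alone (median -2.33, -0.075 after centring), among them CRBN, which encodes cereblon (-2.85), and the lymphoid transcription factor gene IKZF2 (-3.24). Of 17 tested immediate early genes, 0 rose, 16 fell and 1 did not pass (0 and 16 adjusted over the list alone), with a median of -2.63, -0.37 after centring, JUND at -3.99 and BTG1 at -3.98. The stress genes DDIT4, DNAJB1, GADD45A and HSPA8 changed by -5.06, -4.40, -3.59 and -4.29. Of 23 tested p53 target genes, 1 rose, 21 fell and 1 did not pass (1 and 21 adjusted over the list alone). Their median of -2.21 became 0.050 after centring, below the 0.36 of the median gene. The 1 that rose, named after its value was seen, was CDKN1A, which encodes the cell cycle inhibitor p21 (0.95).

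Of 53 tested histone genes, 6 rose, 13 fell and 34 did not pass (5 and 8 adjusted over the list alone), with a median of -0.17 that became 2.09 after centring. Of 77 tested ribosomal protein genes, 0 rose, 71 fell and 6 did not pass (0 and 71 adjusted over the list alone), and the median of -0.74 became 1.51 after centring. Of 67 tested respiratory chain subunit genes, 0 rose, 64 fell and 3 did not pass (0 and 64 adjusted over the list alone), and the median of -1.15 became 1.11. Of 396 tested ZNF-named zinc finger genes, 1 rose, 391 fell and 4 did not pass (1 and 391 adjusted over the list alone), with a median of -2.24 that became 0.019 and with ZNF207 at -3.14. RPS27 changed by -0.57 and ATP5E, an ATP synthase subunit gene, by -0.49, and by 1.69 and 1.76 after centring. On the deposited scale the RPS27 call was lost without DMSO replicate 2 (-0.51) or 3 (-0.51), and the ATP5E call without DMSO replicate 2 (-0.46) or 3 (-0.46) or THAL-SNS-032 replicate 1 (-0.44). Camera placed histone genes (adjusted p = 2.90e-48), ribosomal proteins (4.62e-12) and respiratory chain subunits (0.00224) above the other genes and zinc finger genes below them (0.00360). The adjusted p of these 4 lists with an estimated correlation lay between 0.109 and 0.980, so none held. Across all genes, limma with Benjamini-Hochberg adjustment called 156 genes higher and 10788 lower, 9656 of the latter by at least 2-fold, and after centring the split was 6515 higher and 3319 lower. Among those called higher before centring were 30 short RNAs or unnamed loci and 6 histone genes.

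With NVP-2, CCNT1 fell from 26.8 ± 1.49 to 0.863 ± 0.108 FPKM (-3.90, SE 0.19), MYC from 331 ± 27.4 to 6.73 ± 0.740 and MCL1 from 92.9 ± 6.63 to 6.56 ± 0.620. GATA3 fell to 0.854 ± 0.0531 and HES1 to 0.285 ± 0.0821. CDK7 changed by -4.76, MYB by -4.20, and CDK9 by -2.83, or 0.14 after centring. DDIT4, an inhibitor of mTORC1 signalling, fell from 222 ± 26.5 to 0.546 ± 0.0917, and BRIX1, a ribosome assembly gene, changed by -6.80. HSPA8, XBP1 and LDHA changed by -6.70, -6.56 and -6.30. All 35 tested G1/S and replication genes fell, also adjusted over the list alone (median -3.51, -0.55 after centring), among them PCNA (-5.77) and CDC6, a replication licensing gene (-5.55). All 33 tested G2/M genes fell, also adjusted over the list alone (median -3.33, -0.37 after centring), among them CCNA2, the cyclin A2 gene (-5.67), and CKS2 (-6.13). All 30 tested MYC target genes fell, also adjusted over the list alone (median -3.34, -0.38 after centring). All 33 tested T-lineage genes fell, also adjusted over the list alone, with the surface antigen gene CD2 at -5.88. Their median of -2.88 became 0.082 after centring, below the 0.42 of the median gene. All 12 tested RNA polymerase II subunit genes fell, also adjusted over the list alone, but their median of -2.48 became 0.48, with POLR2D at -4.59. All 19 tested long non-coding RNAs and snoRNA hosts fell, also adjusted over the list alone, but their median of -2.35 became 0.61.

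Of 53 tested histone genes, 15 rose, 16 fell and 22 did not pass (13 and 15 adjusted over the list alone) with NVP-2, and the median of -0.018 became 2.94 after centring. HIST1H1B, a linker histone gene, rose from 1.43 ± 0.430 to 7.69 ± 0.794 FPKM and HIST2H3D from 0.935 ± 0.368 to 5.74 ± 0.702. H1F0 changed by -3.48, and H1FX by -2.86, or 0.10 after centring. TERC, the telomerase RNA, rose from 0.218 ± 0.0129 to 3.66 ± 0.614 and RASL11A from 1.26 ± 0.436 to 7.07 ± 0.531. All 77 tested ribosomal protein genes fell, also adjusted over the list alone, but their median of -1.74 became 1.22 after centring, with RPS27 at -1.43 and RPL17 at -2.90, or 1.53 and 0.064 after centring. Camera placed histone genes (adjusted p = 2.97e-133) and ribosomal proteins (0.00551) above the other genes. With an estimated correlation the histone call held (adjusted p = 0.00425) and the ribosomal call did not (adjusted p = 0.994). On median-centred libraries, an alternative chosen after the data were seen, the estimated correlation lost the histone call too (adjusted p = 0.149). In place of 2 lists, 1 was called without SNS-032 replicate 1, 1 with a replicate block, 7 with equal spike-in medians and 11 after centring. For lists against DMSO, the 10 splits of 6 libraries are too few for a share under 0.05, with a real count of 3 and a highest other of 5 for SNS-032, 4 and 4 for THAL-SNS-032, and 2 and 6 for NVP-2. Across all genes, limma with Benjamini-Hochberg adjustment called 51 genes higher and 11050 lower, 10751 of the latter by at least 2-fold, and after centring the split was 6789 higher and 3198 lower. Of the 51 called higher, 25 were short RNAs or unnamed loci, 15 were histone genes and 11 were other genes.

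**Figure D3:**
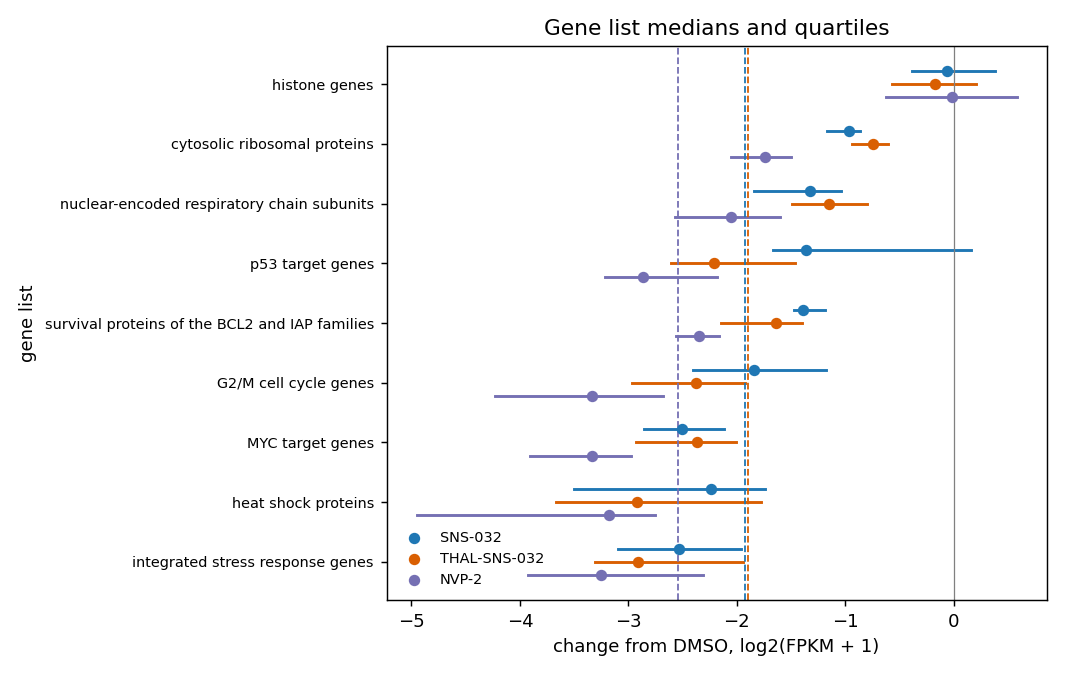
Change from DMSO in log2(FPKM + 1) (horizontal axis) of 9 gene lists (vertical axis) with 3 compounds, where points are medians over tested members, bars run from the lower to the upper quartile and dashed lines mark the median of all tested genes. Histone gene medians are -0.062, -0.17 and -0.018 with SNS-032, THAL-SNS-032 and NVP-2 (after centring 2.11, 2.09 and 2.94), and those of integrated stress response genes are -2.53, -2.91 and -3.25 (after centring -0.36, -0.65 and -0.29).

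THAL-SNS-032 differs from SNS-032 by its cereblon ligand and linker, and both were used at 250 nM for 6 h. MYC was 14.6 ± 2.16 FPKM with THAL-SNS-032 and 145 ± 39.3 with SNS-032 (-3.20, SE 0.20). CCNT1 and CCNT2, cyclin genes of P-TEFb, differed by -1.92 and -1.89, MCL1 by -1.24, GATA3 by -1.76 and HES1 by -2.67, all lower with THAL-SNS-032. B3GNT2 (-3.74), ZNF622 (-3.62) and NOP16 (-3.23) were lower as well. In the other direction, NOTCH1 was 37.0 ± 3.33 with THAL-SNS-032 and 13.9 ± 4.13 with SNS-032, MGP 15.3 ± 1.29 and 1.24 ± 0.367, the chemokine receptor gene CXCR6 6.72 ± 1.18 and 0.700 ± 0.216, and the homeobox gene HHEX 7.64 ± 0.677 and 1.23 ± 0.677, while KRCC1 was higher by 2.36 on the log2 scale. The library medians did not separate the pair (exact two-sided permutation p = 1), which rests on SNS-032 replicate 1. Those of THAL-SNS-032 were -1.96, -1.80 and -1.94, all below SNS-032 replicates 2 and 3 (-1.68 and -1.77) and above replicate 1 (-2.32). For 8754 tested genes (76.9%) the 95% interval of the difference lay within 2-fold, among them CDK9 (-0.022, SE 0.19), XIAP (0.014, SE 0.18), TAL1 (0.14, SE 0.17) and BAX (0.18, SE 0.21), whose differences were -0.25, -0.22, -0.057 and -0.071 without SNS-032 replicate 1 and 0.064, 0.10, 0.22 and 0.27 after centring.

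Of 23 tested p53 target genes, 1 was higher, 15 were lower and 7 did not pass (1 and 15 adjusted over the list alone) with THAL-SNS-032 than with SNS-032 (median -0.995, -0.91 after centring). GADD45A was 0.511 ± 0.0674 FPKM with THAL-SNS-032 and 15.9 ± 6.10 with SNS-032, PPM1D, a p53 phosphatase gene, 1.19 ± 0.208 and 19.9 ± 5.99, SESN1 1.75 ± 0.317 and 24.6 ± 7.23, and BBC3 0.549 ± 0.0341 and 3.82 ± 1.29. Of 33 tested G2/M genes, 1 was higher, 17 were lower and 15 did not pass (2 and 17 adjusted over the list alone), with KIF23 at -2.13 and CCNB1, the cyclin B1 gene, at -1.95. Of 17 tested immediate early genes, 1 was higher, 10 were lower and 6 did not pass (1 and 12 adjusted over the list alone), with IER5 at -1.72. Of 10 tested NF-kB target genes, 1 was higher, 4 were lower and 5 did not pass (1 and 6 adjusted over the list alone), with NFKBIA at -1.88 and TNFAIP3 at -1.57. Of 22 tested SR splicing factors and partners, 0 were higher, 8 were lower and 14 did not pass (0 and 8 adjusted over the list alone), with the kinase gene CLK1 at -2.22. Of 25 tested DNA repair genes reported as sensitive to loss of CDK12, 13 were higher, 3 were lower and 9 did not pass (15 and 4 adjusted over the list alone), with BRIP1 at 0.91 and PALB2 at -1.89. Camera called 12 lists for this pair, among them p53 targets (adjusted p = 8.09e-10), G2/M (1.69e-05), immediate early (1.69e-05), NF-kB (0.00708), SR splicing (0.0157) and these CDK12-sensitive DNA repair genes (0.0168). With an estimated correlation none of the 12 held (adjusted p = 0.995 for each). SNS-032 replicate 1, low across genes, raises that correlation for any list, so this loss alone cannot decide on the lists. On median-centred libraries, an alternative chosen after the data were seen, the estimated correlation kept p53 targets and immediate early genes (adjusted p = 0.0412 for both).

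Between these compounds limma with Benjamini-Hochberg adjustment called 1525 genes higher and 1900 lower with THAL-SNS-032, and after centring 5822 higher and 2629 lower. The count of 3425 changed genes became 2110 with only the 6 libraries of the pair in the fit and 1733 after rescaling to equal spike-in medians. Without SNS-032 replicate 1 it was 4923, and 9222 genes then lay within 2-fold.

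THAL-SNS-032 and NVP-2 are different compounds given at the same dose and time. CKS2, a cell cycle gene, was 106 ± 8.70 FPKM with THAL-SNS-032 and 11.8 ± 1.62 with NVP-2, PCNA 134 ± 9.55 and 30.5 ± 2.41, and MGP 15.3 ± 1.29 and 0.268 ± 0.0939. Of 33 tested G2/M genes, 30 were higher, 1 was lower and 2 did not pass (30 and 1 adjusted over the list alone) with THAL-SNS-032 (median 1.19, 0.48 after centring). Of 35 tested G1/S and replication genes, 30 were higher, 0 were lower and 5 did not pass (30 and 0 adjusted over the list alone) (median 1.18, 0.48 after centring). The RNA-processing genes SF3B4 and HNRNPF were higher by 3.18 and 3.07 on the log2 scale. CCNT1 (1.65), CDK9 (1.04), MCL1 (1.43), GATA3 (1.36) and MYC (1.01, SE 0.20) were higher too, as were NOTCH1 (1.90), the NOTCH pathway gene DTX1 (2.13), HSPA8 (2.41), UQCRFS1 (2.41) and RPL17 (1.59). On this scale the median tested gene was itself higher by 0.64, and it was at -0.065 after centring. The p53 targets AEN (2.15) and CDKN1A (2.01) and the thalidomide-analogue substrate genes IKZF1 (1.78) and CSNK1A1 (2.12) were also higher. HIST1H1B (-1.55) and HIST2H3D (-1.33) were lower. CDK12 (-0.013, SE 0.18), MYB (0.14, SE 0.21) and HEXIM1 (0.35, SE 0.17) did not pass, though HEXIM1 passed without SNS-032 replicate 1 (0.35). After centring they were -0.72, -0.56 and -0.36.

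All 77 tested ribosomal protein genes were higher, also adjusted over the list alone, and all 67 tested respiratory chain subunit genes were higher, also adjusted over the list alone, with THAL-SNS-032 than with NVP-2 (medians 1.01 and 0.91, and 0.30 and 0.20 after centring). Camera placed these lists (adjusted p = 8.36e-06 and 1.92e-04), G2/M (0.00141) and G1/S genes (0.00141) above the other genes, and histone (2.70e-29), zinc finger (0.0170) and NF-kB target genes (0.0450) below them. The zinc finger and NF-kB medians of 0.41 and 0.080 lay above 0 although both lists ranked low, and they became -0.29 and -0.62 after centring. None of these 7 calls held with an estimated correlation (adjusted p = 0.394 to 0.978). Across all genes, limma with Benjamini-Hochberg adjustment called 7969 genes higher and 113 lower with THAL-SNS-032, by a median of 0.64 over tested genes, and after centring the split was 3343 higher and 4327 lower. For 5282 genes (46.4%) the interval of the difference lay within 2-fold, a count of 10130 after centring, 10375 after quantile normalization, and 2618 and 8472 with pseudocounts of 0.1 and 5. SNS-032 replicate 1 is in neither group but widens these intervals through the pooled spread. Without it 6953 genes lay within 2-fold and 9396 were called changed.

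SNS-032 and NVP-2 were also given at the same dose and time. CXCR4, a chemokine receptor gene, was 341 ± 94.2 FPKM with SNS-032 and 6.71 ± 0.637 with NVP-2, NXT1, an RNA export gene, 49.5 ± 20.4 and 0.253 ± 0.00335, BRIX1 57.7 ± 16.5 and 0.781 ± 0.0264, and CKS2 411 ± 112 and 11.8 ± 1.62. MYC (4.21, SE 0.20), HES1 (4.15), CCNT1 (3.56), GATA3 (3.12), MCL1 (2.67) and CDK9 (1.07) were higher with SNS-032. Of 23 tested p53 target genes, 21 were higher, 0 were lower and 2 did not pass (22 and 0 adjusted over the list alone) (median 1.46, 0.67 after centring), with PPM1D at 3.90 and SESN1 at 3.69. Of 33 tested G2/M genes, 29 were higher, 0 were lower and 4 did not pass (30 and 0 adjusted over the list alone) (median 1.45, 0.66 after centring), with CCNB1 at 4.04. Of 11 tested death-promoting BCL2 family genes, 7 were higher, 0 were lower and 4 did not pass (8 and 0 adjusted over the list alone), and the median of 0.67 became -0.12 after centring. CLK1 (4.28), NOP16 (4.35), DDIT4 (3.95), UQCRFS1 (3.68), DNAJB1 (2.85), TNFAIP3 (2.20) and IER2 (2.13) were higher with SNS-032, and HIST1H1B was lower (-1.49). NOTCH1 and CCNL2, a cyclin gene, were higher by 0.52 and 0.75 on the deposited scale, but -0.27 and -0.036 after centring, and HEXIM1 did not pass (-0.10, SE 0.17). The NOTCH1 call was lost without SNS-032 replicate 2 (0.34) or 3 (0.47) or NVP-2 replicate 1 (0.51) or 3 (0.47), and also, with its difference at 0.52, without DMSO replicate 2 or THAL-SNS-032 replicate 1 or 3.

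Camera called 11 lists between SNS-032 and NVP-2, among them histone genes, lower (adjusted p = 2.50e-16), and p53 targets and G2/M genes, higher (adjusted p = 1.89e-07 for both). With an estimated correlation none of the 11 held (adjusted p = 0.897 for each), a loss that SNS-032 replicate 1 affects for any list. None held with that correlation on median-centred libraries either (camera, adjusted p = 0.112 to 0.797). Across all genes, limma with Benjamini-Hochberg adjustment called 5990 genes higher and 89 lower with SNS-032, by a median of 0.48, and after centring the split was 2819 higher and 6706 lower. For 6546 genes (57.5%) the interval of the difference lay within 2-fold. Without SNS-032 replicate 1 the count of changed genes went from 6079 to 9378.

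The calls against DMSO overlapped between compounds. On the deposited scale 10625 genes fell with all 3 compounds, where lists drawn independently would share 9904, and 25 rose with all 3, where independent lists would share 0.0107. Groups simulated without an effect against the same controls shared 0 falling and 0.01 rising genes on average. Few genes can be called in such groups, so these counts cannot show how far shared controls raise the overlap of real calls. Across genes, which are not independent replicates, the log2 changes had a covariance of 0.846 between SNS-032 and THAL-SNS-032, 0.842 between SNS-032 and NVP-2 and 1.07 between THAL-SNS-032 and NVP-2, against 0.0550, 0.0556 and 0.0557 in groups simulated without an effect. The matching correlations were 0.763, 0.717 and 0.878, against 0.496, 0.499 and 0.500. The 3 control libraries are too few to give each compound controls of its own, so part of the overlap may come from sharing them.

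Few markers of other cell types reached the filter. Both tested B-cell markers fell with each compound on the deposited scale, BLK from 48.0 ± 4.46 FPKM in DMSO to 11.5 ± 3.26, 10.8 ± 0.795 and 5.92 ± 0.211 with SNS-032, THAL-SNS-032 and NVP-2, and CD79A from 9.07 ± 0.513 to 3.94 ± 1.48, 5.73 ± 0.515 and 2.81 ± 0.213, but after centring BLK turned to 0.16, 0.20 and 0.14 and CD79A to 1.09, 1.67 and 1.56. VIM, the only tested gene of the fibroblast list and one that leukocytes also express, changed by -2.16, -1.89 and -2.74, but by 0.015, 0.37 and 0.22 after centring. After centring BLK still lay below the median gene with each compound, and VIM with SNS-032 and NVP-2. Of the myeloid list, CD14 rose from 0.413 ± 0.0226 to 2.08 ± 0.718 with SNS-032 and 1.63 ± 0.307 with THAL-SNS-032 and did not pass with NVP-2 (-0.11, 2.85 after centring). FCER1G rose from 1.32 ± 0.925 to 2.41 ± 0.838 with SNS-032, did not pass with THAL-SNS-032 (-0.081, 2.18 after centring) and was 0.184 ± 0.0834 with NVP-2, a change of -0.90 that was -0.60 without DMSO replicate 3 and turned to 2.06 after centring. Its rise with SNS-032, 0.60, lost its call without DMSO replicate 1 (0.34) or 2 (0.56) or SNS-032 replicate 2 (0.50) or 3 (0.48), and was 0.90 without DMSO replicate 3. No gene of the erythroid or epithelial lists reached the filter, and the table holds none of the mitochondrially encoded genes under the names searched.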

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

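Some genes moved in opposite directions from DMSO with different compounds on the deposited scale, with the direct difference between the compounds passing (limma). There were 16 genes higher with SNS-032 and lower with THAL-SNS-032, 14 higher with THAL-SNS-032 and lower with SNS-032, 57 higher with THAL-SNS-032 and lower with NVP-2, and 68 higher with SNS-032 and lower with NVP-2. Examples, named after their values were seen, include SESN1 (0.63 with SNS-032, -2.55 with THAL-SNS-032), TP53INP1 (1.63, -0.69) and CHRNA10 (-0.63, 1.56). With NVP-2, CXCR6 was -0.34 against 2.47 with THAL-SNS-032, CDKN1A -1.06 against 0.95, and the zinc transporter gene SLC30A1 -1.02 against 2.50 with SNS-032. The fall of CXCR6 with NVP-2 lost its call without DMSO replicate 1 (-0.25) or NVP-2 replicate 1 (-0.34) or 2 (-0.33). On median-centred libraries SESN1 kept opposite signs (-0.30 with THAL-SNS-032) and the other 5 lay above 0 with both compounds, while after quantile normalization CXCR6 and CDKN1A with NVP-2 were -0.033 and -0.17 without passing.

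The lower p53 target genes with THAL-SNS-032 than with SNS-032 were weighed further, and the tests of SNS-032 replicate 1 and of low values were chosen after the result was seen. The list lay -1.13 from the median of all genes (spread 0.30), with 15 of 23 members lower and 1 higher. Spread here is an approximate SE of a median that takes the genes as independent, which they are not. The members themselves ranged more widely, with quartiles of their differences at -1.79 and -0.34. Camera lost this list with an estimated correlation (adjusted p = 0.995) and called it with that correlation on median-centred libraries (adjusted p = 0.0412), where its median was -0.91. The library median of SNS-032 replicate 1 lay -0.60 from the mean of replicates 2 and 3, whose own gap was 0.10. A low SNS-032 library raises the difference on the deposited scale and does not lower it. This cannot decide on the list less all genes, since a shift of a whole library moves both about alike, and the library medians were known beforehand. Without that replicate the list lay -1.20 from the median of all genes (spread 0.31), with 20 members lower and 1 higher. Values near the floor stay open. The 6 members with a mean of 5 FPKM or more in both groups lay -0.82 from the median of all genes with a spread of 0.34, and 3 of them were lower. That choice drops members that fell far with THAL-SNS-032, GADD45A and SESN1 among them, so its smaller difference cannot decide. The 20 with such a mean in DMSO, a choice that uses neither compound, lay at -1.13 (spread 0.31). A different response of these genes to the compounds may also remain and was not tested.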

How the results depend on the processing

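Chosen after the data were seen were centring on the median change from DMSO, leaving out short RNAs and unnamed loci, and the estimated correlation on median-centred libraries. Limma without trend or with robust moved no count by over 1.5 times, and camera does not use the trend, so these settings leave list calls as they are. Leaving out short RNAs and unnamed loci was run for the 6 totals of changed genes alone and moved none by over 1.5 times, although 25 of the 51 genes that rose with NVP-2 are of that kind. Of 2427 values of named genes under the other settings 2286 kept direction and call, 84 reversed, 17 lost a call, 16 gained one and 24 not called as reported changed sign, 18 of which passed in the new direction. Of 2460 with 1 library left out the numbers were 2424, 0, 19, 4, 13 and 0. Reversals under centring or quantile normalization follow from taking out a shift of all genes and do not test changes on the deposited scale. Under the stricter filter 33 gene values could not be given. Of 18 pairs of libraries with the same replicate number 1 correlated by over 0.1 (range -0.15 to 0.17), and in 8 the same number was the best partner. The pairs share libraries, and these values cannot show whether the numbers mark a shared day or culture. Depth is unknown and sets no limit that can be given. Counts are listed where they moved by over 1.5 times, and medians for settings in which at least 1 moved by over the SD between libraries. The cause of each difference was not tested, except where fewer or more genes are tested, a size is required, libraries are rescaled or the test asks another question.

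The counts of changed genes, 10936 (SNS-032 against DMSO), 10944 (THAL-SNS-032 against DMSO), 11101 (NVP-2 against DMSO), 3425 (THAL-SNS-032 against SNS-032), 8082 (THAL-SNS-032 against NVP-2) and 6079 (SNS-032 against NVP-2), became 19614 (NVP-2 against DMSO) with no filter. With median-centred libraries they were 8451 (THAL-SNS-032 against SNS-032) and 9525 (SNS-032 against NVP-2). With quantile normalization they were 8850 (THAL-SNS-032 against SNS-032) and 9447 (SNS-032 against NVP-2). With equal ERCC medians it was 1733 (THAL-SNS-032 against SNS-032). With only the 6 libraries of the pair it was 2110 (THAL-SNS-032 against SNS-032). With centring on the median change from DMSO it was 7866 (THAL-SNS-032 against SNS-032). With a 2-fold minimum they were 976 (THAL-SNS-032 against SNS-032), 2286 (THAL-SNS-032 against NVP-2) and 2633 (SNS-032 against NVP-2).

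The median log2 changes of -1.92, -1.90 and -2.54 became -1.40 (SNS-032 against DMSO), -1.39 (THAL-SNS-032 against DMSO) and -1.82 (NVP-2 against DMSO) with a pseudocount of 5. With no filter they were -0.53 (SNS-032 against DMSO), -0.52 (THAL-SNS-032 against DMSO) and -0.78 (NVP-2 against DMSO). With median-centred libraries they were 0.25 (SNS-032 against DMSO), 0.36 (THAL-SNS-032 against DMSO) and 0.42 (NVP-2 against DMSO). With quantile normalization they were 0.0080 (SNS-032 against DMSO), 0.074 (THAL-SNS-032 against DMSO) and 0.10 (NVP-2 against DMSO). With centring on the median change from DMSO they were 0.0029 (SNS-032 against DMSO), 0.0029 (THAL-SNS-032 against DMSO) and 3.3e-04 (NVP-2 against DMSO). With a pseudocount of 0.1 they were -2.19 (SNS-032 against DMSO), -2.14 (THAL-SNS-032 against DMSO) and -2.97 (NVP-2 against DMSO). With a mean of 5 FPKM or more they were -2.05 (SNS-032 against DMSO), -2.02 (THAL-SNS-032 against DMSO) and -2.81 (NVP-2 against DMSO). With equal ERCC medians they were -1.95 (SNS-032 against DMSO), -1.96 (THAL-SNS-032 against DMSO) and -2.63 (NVP-2 against DMSO).

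The counts of genes within 2-fold became 20832 (THAL-SNS-032 against SNS-032), 17323 (THAL-SNS-032 against NVP-2) and 18611 (SNS-032 against NVP-2) with no filter. With an interval of 1.5-fold they were 3519 (THAL-SNS-032 against SNS-032), 1861 (THAL-SNS-032 against NVP-2) and 2918 (SNS-032 against NVP-2). With a pseudocount of 0.1 it was 2618 (THAL-SNS-032 against NVP-2). With a pseudocount of 5 it was 8472 (THAL-SNS-032 against NVP-2). With a mean of 5 FPKM or more they were 2579 (THAL-SNS-032 against NVP-2) and 3931 (SNS-032 against NVP-2). With median-centred libraries it was 10130 (THAL-SNS-032 against NVP-2). With quantile normalization it was 10375 (THAL-SNS-032 against NVP-2). With centring on the median change from DMSO it was 10242 (THAL-SNS-032 against NVP-2).

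The list counts, 3 (SNS-032 against DMSO), 4 (THAL-SNS-032 against DMSO), 2 (NVP-2 against DMSO), 12 (THAL-SNS-032 against SNS-032), 7 (THAL-SNS-032 against NVP-2) and 11 (SNS-032 against NVP-2), became 20 (SNS-032 against DMSO), 25 (THAL-SNS-032 against DMSO), 26 (NVP-2 against DMSO), 11 (THAL-SNS-032 against NVP-2) and 19 (SNS-032 against NVP-2) with no filter. With median-centred libraries they were 7 (SNS-032 against DMSO), 10 (THAL-SNS-032 against DMSO) and 11 (NVP-2 against DMSO). With quantile normalization they were 5 (SNS-032 against DMSO), 12 (THAL-SNS-032 against DMSO), 11 (NVP-2 against DMSO) and 4 (THAL-SNS-032 against NVP-2). With centring on the median change from DMSO they were 6 (SNS-032 against DMSO), 9 (THAL-SNS-032 against DMSO) and 8 (NVP-2 against DMSO). With an estimated correlation in camera they were 0 (SNS-032 against DMSO), 0 (THAL-SNS-032 against DMSO), 1 (NVP-2 against DMSO), 0 (THAL-SNS-032 against SNS-032), 0 (THAL-SNS-032 against NVP-2) and 0 (SNS-032 against NVP-2). With fry they were 23 (SNS-032 against DMSO), 23 (THAL-SNS-032 against DMSO), 23 (NVP-2 against DMSO), 3 (THAL-SNS-032 against SNS-032), 22 (THAL-SNS-032 against NVP-2) and 23 (SNS-032 against NVP-2). With that correlation on median-centred libraries they were 0 (SNS-032 against DMSO), 0 (THAL-SNS-032 against DMSO), 0 (NVP-2 against DMSO), 2 (THAL-SNS-032 against SNS-032), 0 (THAL-SNS-032 against NVP-2) and 0 (SNS-032 against NVP-2). With equal ERCC medians it was 7 (NVP-2 against DMSO). With a replicate block it was 1 (NVP-2 against DMSO). With a mean of 5 FPKM or more it was 7 (SNS-032 against NVP-2).

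With median-centred libraries, 35 of 205 named gene values reversed, namely CDK9 0.41, MYC 0.96, MCL1 1.20, GATA3 1.20, RPS27 1.34, POLR2A 0.31, RPL4 0.45, BCL2 0.70, BLK 0.16, CD79A 1.09, VIM 0.015 and CHRNA10 1.54 (SNS-032 against DMSO); MCL1 0.048, CDK9 0.48, CCNT1 0.0053, NOTCH1 0.64, RPS27 1.69, ATP5E 1.76, BLK 0.20, CD79A 1.67, VIM 0.37 and TP53INP1 1.57 (THAL-SNS-032 against DMSO); CDK9 0.14, RPS27 1.53, RPL17 0.064, H1FX 0.10, BLK 0.14, CD79A 1.56, VIM 0.22, FCER1G 2.06, CXCR6 2.62, CDKN1A 1.90 and SLC30A1 1.94 (NVP-2 against DMSO); NOTCH1 -0.27 and CCNL2 -0.036 (SNS-032 against NVP-2).

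With quantile normalization, 25 of 205 named gene values reversed, namely CDK9 0.38, MYC 0.43, MCL1 1.07, GATA3 1.17, POLR2A 0.25, BCL2 0.31, BLK 0.12, CD79A 0.85 and CHRNA10 0.65 (SNS-032 against DMSO); CDK9 0.43, CCNT1 0.0087, NOTCH1 0.34, RPS27 0.066, ATP5E 0.44, BLK 0.14, CD79A 1.39 and TP53INP1 0.70 (THAL-SNS-032 against DMSO); CDK9 0.18, RPS27 0.066, BLK 0.18, CD79A 1.29, FCER1G 0.12 and SLC30A1 0.66 (NVP-2 against DMSO); NOTCH1 -0.38 and CCNL2 -0.036 (SNS-032 against NVP-2).

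With centring on the median change from DMSO, 24 of 205 named gene values reversed, namely CDK9 0.17, MYC 0.71, MCL1 0.96, GATA3 0.96, RPS27 1.09, POLR2A 0.061, RPL4 0.21, BCL2 0.46, CD79A 0.85 and CHRNA10 1.29 (SNS-032 against DMSO); CDK9 0.12, NOTCH1 0.29, RPS27 1.33, ATP5E 1.41, CD79A 1.32, VIM 0.018 and TP53INP1 1.21 (THAL-SNS-032 against DMSO); RPS27 1.11, CD79A 1.14, FCER1G 1.64, CXCR6 2.19, CDKN1A 1.48 and SLC30A1 1.52 (NVP-2 against DMSO); NOTCH1 -0.094 (SNS-032 against NVP-2).

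Calls of named genes were lost for RPS27 (SNS-032 against DMSO, with quantile normalization), RPS27 (THAL-SNS-032 against DMSO, with no filter), NOTCH1 (SNS-032 against NVP-2, with a pseudocount of 5, no filter, equal ERCC medians and only the 6 libraries of the pair), CCNL2 (SNS-032 against NVP-2, with centring on the median change from DMSO), ATP5E (THAL-SNS-032 against DMSO, with no filter and equal ERCC medians), BLK (SNS-032 against DMSO, with centring on the median change from DMSO), FCER1G (SNS-032 against DMSO, with no filter, equal ERCC medians and limma with robust), CXCR6 (NVP-2 against DMSO, with a pseudocount of 5, quantile normalization and equal ERCC medians) and CDKN1A (NVP-2 against DMSO, with quantile normalization). Calls were gained for BIRC5 (SNS-032 against DMSO, limma without trend, limma with robust and a replicate block), XIAP (THAL-SNS-032 against SNS-032, with quantile normalization), TAL1 (THAL-SNS-032 against SNS-032, with median-centred libraries and quantile normalization), BAX (THAL-SNS-032 against SNS-032, with median-centred libraries and centring on the median change from DMSO), CDK12 (THAL-SNS-032 against NVP-2, with median-centred libraries, quantile normalization and centring on the median change from DMSO), HEXIM1 (THAL-SNS-032 against NVP-2, with only the 6 libraries of the pair and a replicate block) and HEXIM1 (SNS-032 against NVP-2, with median-centred libraries, quantile normalization and centring on the median change from DMSO). Calls in the opposite direction, for genes not called as reported, were gained by CCNT1 (SNS-032 against DMSO, 1.83 with median-centred libraries, 1.81 with quantile normalization and 1.59 with centring on the median change from DMSO), BIRC5 (SNS-032 against DMSO, 1.74 with median-centred libraries, 1.41 with quantile normalization and 1.49 with centring on the median change from DMSO), MYB (THAL-SNS-032 against NVP-2, -0.56 with median-centred libraries, -0.70 with quantile normalization and -0.50 with centring on the median change from DMSO), HEXIM1 (THAL-SNS-032 against NVP-2, -0.36 with median-centred libraries, -0.46 with quantile normalization and -0.29 with centring on the median change from DMSO), CD14 (NVP-2 against DMSO, 2.85 with median-centred libraries, 0.65 with quantile normalization and 2.42 with centring on the median change from DMSO) and FCER1G (THAL-SNS-032 against DMSO, 2.18 with median-centred libraries, 0.92 with quantile normalization and 1.82 with centring on the median change from DMSO).

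Leaving out 1 library at a time gave 10876 to 10989 changed genes (SNS-032 against DMSO), 10844 to 11021 changed genes (THAL-SNS-032 against DMSO), 11077 to 11116 changed genes (NVP-2 against DMSO), 2314 to 4923 changed genes (THAL-SNS-032 against SNS-032), 6652 to 9396 changed genes (THAL-SNS-032 against NVP-2) and 4673 to 9378 changed genes (SNS-032 against NVP-2). The medians ranged over -2.05 to -1.72 (SNS-032 against DMSO), -1.95 to -1.86 (THAL-SNS-032 against DMSO) and -2.58 to -2.49 (NVP-2 against DMSO), the genes within 2-fold over 7935 to 9222 (THAL-SNS-032 against SNS-032), 4314 to 6953 (THAL-SNS-032 against NVP-2) and 5588 to 7360 (SNS-032 against NVP-2) and the lists over 3 in each fit (SNS-032 against DMSO), 3 to 5 (THAL-SNS-032 against DMSO), 1 to 3 (NVP-2 against DMSO), 8 to 12 (THAL-SNS-032 against SNS-032), 6 to 8 (THAL-SNS-032 against NVP-2) and 11 to 12 (SNS-032 against NVP-2). Only without SNS-032 replicate 1 did a count move by over 1.5 times, to 9378 changed genes (SNS-032 against NVP-2) and 1 list (NVP-2 against DMSO).

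Each pair of groups has 10 splits of its 6 libraries, too few for a share under 0.05. Every other split mixes libraries of both groups, so a difference between the groups widens the spread and few genes can be called there. The gap between the real gene count and the others is thus no added support. For changed genes 1 split, the real one, gave as many in each comparison, and the real and highest other counts were 10936 and 2 (SNS-032 against DMSO), 10944 and 1 (THAL-SNS-032 against DMSO), 11101 and 2 (NVP-2 against DMSO), 3425 and 2 (THAL-SNS-032 against SNS-032), 8082 and 1 (THAL-SNS-032 against NVP-2) and 6079 and 1 (SNS-032 against NVP-2). For lists, the splits with as many, the real count and the highest other were 7, 3 and 5 (SNS-032 against DMSO), 5, 4 and 4 (THAL-SNS-032 against DMSO), 6, 2 and 6 (NVP-2 against DMSO), 1, 12 and 8 (THAL-SNS-032 against SNS-032), 1, 7 and 5 (THAL-SNS-032 against NVP-2) and 1, 11 and 9 (SNS-032 against NVP-2).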

Other observations

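Short RNAs moved in both directions on the deposited scale. Of 90 tested microRNA genes, 13 rose and 17 fell with SNS-032 (median -0.015), 11 rose and 15 fell with THAL-SNS-032 (median -0.28) and 3 rose and 19 fell with NVP-2 (median -0.10). Of 150 small nucleolar RNAs, 16 rose and 37 fell with SNS-032 (median -0.26), 7 rose and 55 fell with THAL-SNS-032 (median -1.96) and 11 rose and 57 fell with NVP-2 (median -1.60). Of 16 small Cajal body RNAs, 4 rose and 2 fell with SNS-032 (median 0.73), 4 rose and 4 fell with THAL-SNS-032 (median 0.049) and 7 rose and 3 fell with NVP-2 (median 1.03). Named after their values were seen, RNU11, a minor spliceosome RNA, rose by 5.69, 4.44 and 6.21 on the log2 scale with SNS-032, THAL-SNS-032 and NVP-2, and RPPH1, the RNA of RNase P, rose from 6.27 ± 4.54 FPKM to 119 ± 56.9, 91.7 ± 5.97 and 122 ± 14.7. MIR3648 changed by 8.53, 7.67 and 7.10 and MIR663A by 9.33, 9.17 and 8.19 (the last 5.30 without DMSO replicate 1), and FPKM of such short transcripts is uncertain.

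Histone gene medians stayed near 0 on the deposited scale while the median of all genes fell, and the test of RNAs without a poly(A) tail was chosen after this was seen. Their level and transcript length are argued against as the whole account, since the histone median lay at or above the 99.99 percentile of 10000 random lists matched for both with each compound. The matched lists had medians of -0.86, -0.86 and -1.23 with SNS-032, THAL-SNS-032 and NVP-2, against -1.92, -1.90 and -2.54 for all genes. Level and length may thus account for part of the gap. Carry-over of RNA without a poly(A) tail through selection, whose share would rise as other RNA falls, is a candidate explanation that the values leave open. The 22 tested RNAs without a tail had medians of 0.95, 0.049 and 1.71 with SNS-032, THAL-SNS-032 and NVP-2, the lowest being 0.0486. The 9 polyadenylated variant histone genes had -2.09, -2.28 and -2.92. Their median DMSO level was 258 FPKM, against 2.43 for the histone list and 2.26 for the RNAs without a tail. The scale understates falls from low levels, so this contrast is mixed with level. The 150 small nucleolar RNAs, which also lack a tail, had -0.26, -1.96 and -1.60, or 1.67, -0.058 and 0.94 from the median of all genes. Carry-over alone would keep them above the median of all genes, which was so with SNS-032, less so with NVP-2 and not with THAL-SNS-032. A fall of these RNAs themselves under the compounds was not told apart from it, so this class cannot decide. Continued transcription or slow decay of histone transcripts was not tested and stays open.

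SNS-032 replicate 1 lay below replicates 2 and 3 across genes. Over 3803 genes with a mean of 20 FPKM or more, which are not independent, its gap to replicate 3 had a median of -0.73 and an interquartile range of 0.0873, and 99.3% of genes lay below 0. A stronger response to the compound in that library is argued against by the slope of this gap on the change of replicate 2 from DMSO, 0.0427 (bootstrap 95% interval -0.0487 to 0.141), and the upper bound used to read that test was added after the slope was seen. A difference in the scale of the library may account for the gap, and whether it arose in the culture, the spike-in or the sequencing was not tested.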
